A study of Mus musculus with 16 samples.

How the data were processed

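Total liver RNA of 16 male mice (7 Lactb transgenic, 9 FVB wildtype) was turned into biotin-labelled cRNA and read on Illumina bead arrays, per the submitters' protocols. The header of a further deposited table names the array content as the first version of the Mouse Ref-8 design. The deposited value table holds 24048 probes as intensity on a linear scale, 1 column per animal. The submitters' processing notes name BeadStudio 1.5.1.3, and how the deposited intensities were scaled is not given in the sources used here. From the values, background had been subtracted (30.0% to 33.8% of each array's values lie below 0) and the arrays had been brought to a common mean of 331.4 to 333.5. The deposited intensities had not been quantile normalized and were not on a log scale. The further table, unnormalized per the file headers, names its 128 per-sample columns by chip position alone. No label ties these to animals, so it was not used here. Its detection values and slide positions therefore played no part.

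The planned background correction from detection values could not be run without that table. In its place the deposited intensities were corrected with the normexp model fitted to each array by itself (saddle-point fit, offset 16), put on a log2 scale and quantile normalized in limma 3.58.1 (R 4.3.3). A probe was called detected on an array when its deposited intensity exceeded 1.645 times the noise SD of that array, taken as the root mean square of its negative values (10.4 to 19.7 intensity units, so a limit of 17.1 to 32.5). Probes detected on at least 6 arrays were tested. The planned slide block was not run. Quantile normalization forces equal distributions, so a shift shared by most genes would not be seen, and folds of dim probes are compressed by the offset.

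No table of probe names for this array was used. The padded number in 9523 probe identifiers was matched to the gene identifiers of a RefSeq table of assembly GRCm38.p6, which named 8884 probes (93.3%), and 9 more probes carry a RefSeq accession. This reading of the identifiers was checked on the data. Six-digit numbers matched in 91.3% of cases, against 7.1% after adding 1000 to each. Of 353 probes so named as olfactory or vomeronasal receptors 10.5% were detected, and of 55 ribosomal protein probes 100% were. For 391 genes with at least 2 detected probes the median correlation of a pair of probes across arrays was 0.47, against 0.05 for random pairs. In all 7413 genes were named, and 15155 probes stayed without a name and were tested by identifier alone. No probe could be named Lactb (0 probes), so the planned reading of the transgene product was not made. A gene was read by its named probe of highest mean.

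Genotypes were compared with lmFit and eBayes in limma (two-sided, Benjamini-Hochberg over all tested probes, threshold 0.05), with no covariates. Gene lists with at least 5 measured members were tested with camera (preset inter-gene correlation 0.01, Benjamini-Hochberg over the lists), with an estimated correlation and with fry. A count adjusted over the list alone applies Benjamini-Hochberg to the members of 1 list. The 41 lists (27 of pathways, 13 of cell types and a male check) and the rule for named genes were fixed before the data were examined. The rule takes Lactb, then up to 24 genes, by size of change among those past the threshold and otherwise by smallest p, then for each list up to 4 members that pass or the 2 of smallest p. Features without a gene symbol are counted, and named only among the first 3 of their direction. The single comparison of the main axis used an exact permutation test over 11440 splits, and title numbers permutation tests with 100000 resamples, over all animals and within genotypes. Levels are means ± SD on the log2 scale, differences are transgenic minus wildtype with the moderated SE, and SD over animals includes biological and technical spread.

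The fit was tested on simulated data. In 20 draws over 11317 probes with 200 changed and the real arrays' residuals kept together, 77.0% of 1.5-fold, 93.6% of 2-fold and 99.0% of 3-fold changes were recovered, with a median of 1.5 false calls (at most 33). The changes were added to the log2 values after background correction, offset and normalization. Recovery of RNA folds on dim probes, which the offset compresses, is therefore overstated. Recovery also depends on how many probes change, and numbers other than 200 were not simulated. In 20 draws of 24 lists of 14 genes, simulated as independent probes, the list shifted by 0.3 was called 20 times and unchanged lists 0 times. Members of real lists vary together (estimated correlation 0.38 to 0.54 for the 3 lists called here). This simulation therefore does not give the rate of false list calls in these data. Alternatives covered background correction, offset, normalization, the authors' values as deposited, the probe filter, the title number as a block, array weights, the variance model, the probe per gene, the set test, and each animal left out in turn. The main axis as a covariate, the title number within a genotype as a random block, residual components as covariates and a fit without the 2 animals between the ends of the axis were added after seeing the data. Statistics were computed in R (statmod 1.5.0) and Python 3.11.15 (pandas 2.3.3, numpy 2.4.6, matplotlib 3.10.9). The number of arrays limits the precision.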

Results

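Liver RNA from 16 male FVB mice was measured on bead arrays, with 7 animals carrying a Lactb transgene and 9 wildtype animals of the background strain. Lactb encodes a serine protease-like protein of mitochondria that is related to bacterial penicillin-binding proteins. All animals were 23 weeks old, and had been moved at 11 weeks from a chow diet with 4% fat to a chow diet with 6% fat. Each array gave a background-subtracted intensity for 24048 probes, of which 9907 to 11564 stood above the noise of their array. A gene name could be attached to 8893 probes (37.0%), and no named probe read Lactb, so the level of the transgene product in each animal was not analysed here and the labels stand without that check. The arrays correlated with each other at 0.961 to 0.991 across probes, and no pair shared over 0.3% identical values, so no array was a copy of another. Each array was counted as a separate animal, which this check cannot show. Some arrays of a genotype share a title number, and what the number stands for is not given in the labels used here.

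The comparison asks which liver transcripts differ when Lactb is carried as a transgene. No probe passed the threshold: limma called 0 of 11317 probes, 332 had an unadjusted p under 0.05 (2.9%, where 5% is expected by chance), and the lowest adjusted p was 0.932. That count of 332 ran from 219 to 797 when single animals were left out, and was 1509 with the title number as a fixed block. In the fixed-block fit the difference rests only on title numbers that occur in both genotypes. For numbers 12 and 13 the transgenic and wildtype animals lay at opposite ends of the main axis of variation described below. The count of that fit is therefore not a measure of genotype alone. Among the 3971 named genes measured, the smallest p belonged to Gstm2, a glutathione S-transferase of the mu class. Its level was 12.42 ± 0.60 (SD, n = 7) on the log2 scale in transgenic liver and 11.49 ± 0.54 (SD, n = 9) in wildtype liver. This difference of 0.93 (SE 0.26) is a 1.90-fold higher mean, with all 7 transgenic animals above the wildtype mean. The limma adjusted p of Gstm2 was 0.932 over all probes, and 0.0295 when adjusted over the list alone for the NRF2 target list, the only list member in any list to pass in that way. The p-values measure the spread between animals taken as independent. Animals of a genotype that share a title number had an estimated correlation of 0.379, which these p-values leave out. Another Gstm2 probe gave a difference of 0.92 (SE 0.26).

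The 24 named genes of smallest p comprised 8 with a higher and 16 with a lower mean in transgenic liver. None passed the threshold, their unadjusted p reached 0.0107, and their folds ran from 1.12 to 1.90. With a higher mean than in wildtype liver stood, after Gstm2, Lrrc24 (leucine-rich repeat protein; log2 difference 0.70, SE 0.22), Rnd2 (0.34), Dusp19 (dual-specificity phosphatase; 0.31), Rpap3 (co-chaperone of RNA polymerase II assembly; 0.31), Cpd (carboxypeptidase D; 0.27), Appl1 (adaptor that binds adiponectin receptors; 0.25) and Pus1 (pseudouridine synthase; 0.23). With a lower mean stood Cyp2c23, a cytochrome P450 that makes epoxides of arachidonic acid. Its level was 13.13 ± 0.12 (SD, n = 7) against 13.36 ± 0.12 (SD, n = 9), and all 7 transgenic animals lay below the wildtype mean. Prox1, a homeobox regulator of hepatocyte identity, differed by -0.22 (SE 0.072), and Mocs1, an enzyme of molybdenum cofactor synthesis, by -0.22 (SE 0.064). Also lower were the means of Prdm2 (-0.32), Zfp871 (-0.31), Akap8l (-0.29), Zfc3h1 (-0.25), Atxn2 (-0.25), Larp4b (-0.22) and Zfp318 (-0.21). The remaining genes of this set were Lefty1 (-0.33), Cobll1 (-0.30), Catsperz (-0.28), Pkhd1l1 (-0.24), Dpm1 (-0.21; another probe of Dpm1 gave -0.11) and Arhgef11 (-0.17). Of these 24 genes, 6 were not above background on every array, so the size of their difference is uncertain: Lefty1 and Pkhd1l1 (6 of 16 arrays each), Rpap3 (10), Catsperz (11), Lrrc24 and Rnd2 (13 each). A further 21 features without a usable name had a p as small. The probes scl32723.5.1_67-S (0.47, SE 0.10), scl49624.7.1_29-S (-0.25, SE 0.066) and scl44261.19.1_20-S (-0.25, SE 0.070) were among the first 3 of their direction.

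**Figure D1:**
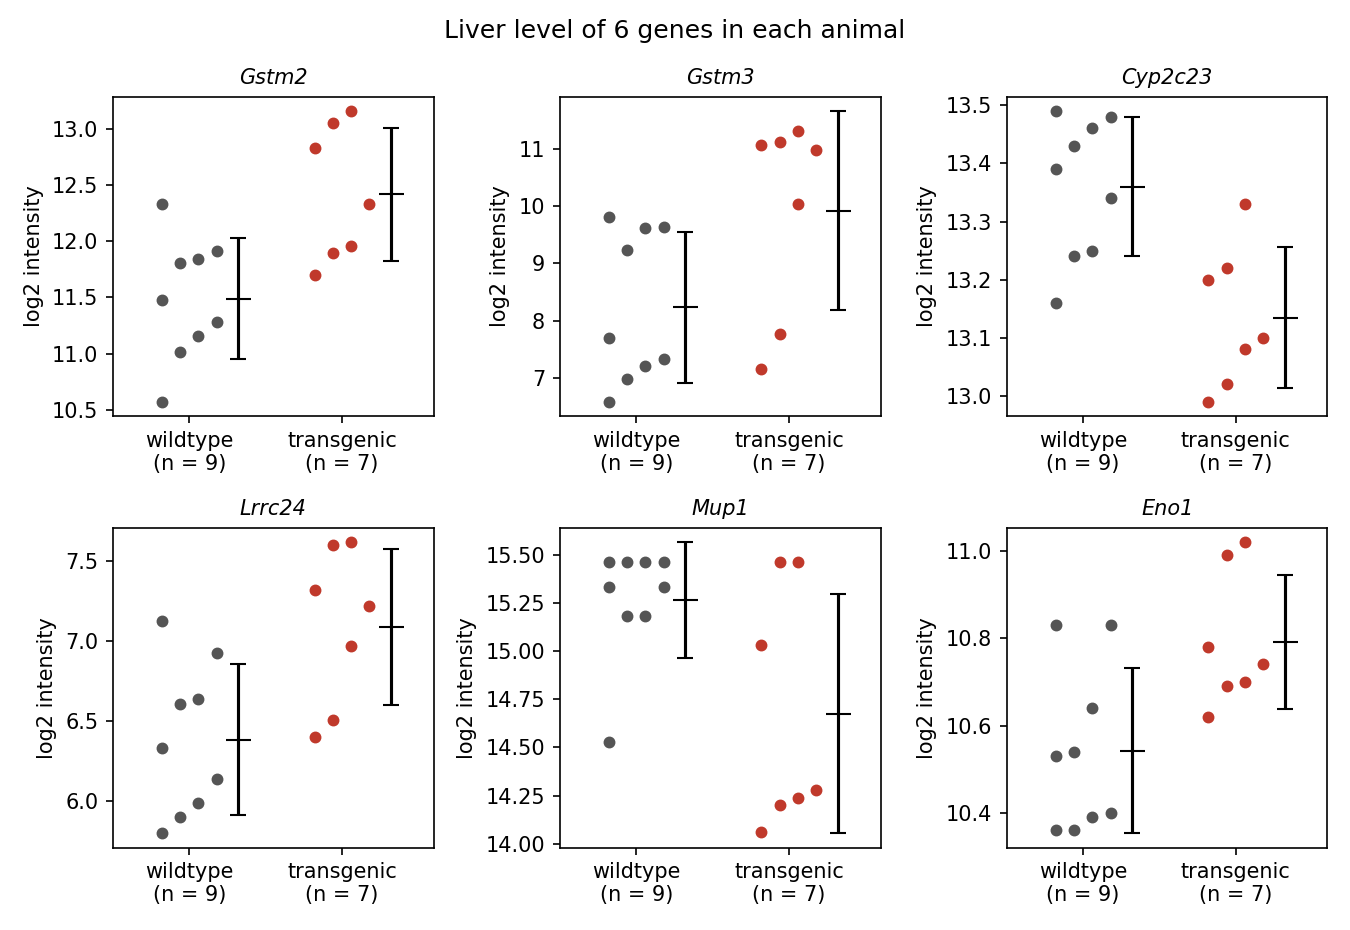
Log2 intensity of Gstm2, Gstm3, Cyp2c23, Lrrc24, Mup1 and Eno1 in each animal, with wildtype in grey and transgenic in red; the bar beside the points is the mean and the whiskers are 1 SD. Gstm2 averaged 12.42 in transgenic and 11.49 in wildtype liver, and the animals of the 2 groups overlap for all 6 genes.

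The 95% interval of the difference lay within a 2-fold change either way for 97.4% of the probes and within a 1.5-fold change for 90.5%. On simulated arrays of this size and spread, with 200 changed probes, limma recovered 77.0% of 1.5-fold changes and 93.6% of 2-fold changes. Those changes were added after normalization. The intervals and the simulation both refer to log2 values in which the offset compresses folds of dim probes. For dim probes these shares therefore overstate how well a fold in RNA was bounded or recovered. With fewer than 200 changed probes the adjusted threshold is stricter and recovery lower, which was not simulated. The 299 probes whose interval reached beyond a 2-fold change include Mup2, Mup4, Gstm3 and Gpnmb, genes with a wide spread inside each group that vary along the main axis of variation. No tested probe was higher in every transgenic than in every wildtype array. A single unnamed probe, scl49624.7.1_29-S, was lower in all of them, where chance gives 2 such probes in the 2 directions together. The number of arrays limits the precision.

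Of the 40 gene lists fixed before the data were examined, 24 had at least 5 measured members, and camera with its preset correlation called 3 of them. NRF2 targets, genes of glutathione conjugation and antioxidant defence, shifted upward, with 13 of 14 members higher in transgenic liver and a median difference of 0.29 (adjusted p = 4.61e-05, and adjusted p = 0.459 with an estimated correlation). Besides Gstm2, its members included Gstm3 (1.69, SE 0.68), Gsta1 (0.97, SE 0.61), Srxn1 (0.59) and Pgd of the pentose phosphate pathway (0.46). The metallothionein Mt1 was the exception at -0.33. Over all probes 0 of its 14 members passed, and 1 passed when adjusted over the list alone. Cytosolic ribosomal protein genes also shifted upward by a small amount, with 41 of 45 members higher and a median of 0.061 (adjusted p = 4.61e-05, and adjusted p = 0.79 with an estimated correlation). The smallest p among them were those of Rpl12 (0.22) and Rpl13 (0.16), and 0 members passed over all probes or adjusted over the list alone.

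Genes with higher expression in male than in female liver shifted downward, with 11 of 12 members lower in transgenic liver and a median of -0.24 (adjusted p = 0.0179, and adjusted p = 0.79 with an estimated correlation). This call was lost with the title number within a genotype as a random block (adjusted p = 0.0511, an alternative chosen after seeing the data), on probes detected on all arrays (adjusted p = 0.0515) and without any 1 of 5 animals. Mup1, a major urinary protein, had a mean of 14.67 ± 0.62 (SD, n = 7) against 15.27 ± 0.30 (SD, n = 9), a difference of -0.59 (SE 0.21). Igfals, the subunit that stabilises circulating IGF complexes, differed by -0.42 (SE 0.22). Neither passed over all probes or adjusted over the list alone (0 of 12 members). Mup1 is among the brightest probes, and its level on 6 arrays was the ceiling of 15.46 that quantile normalization sets. The Mup genes are near-identical copies, so a probe of Mup1 or Mup4 may also read its relatives. With an estimated correlation camera called 0 of the 24 lists (lowest adjusted p = 0.365), and fry, which asks whether a list moves on balance in either direction, called 0 (lowest adjusted p = 0.332). The members of these 3 lists also vary along the main axis of variation, on which the transgenic arrays lay higher on average.

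**Figure D2:**
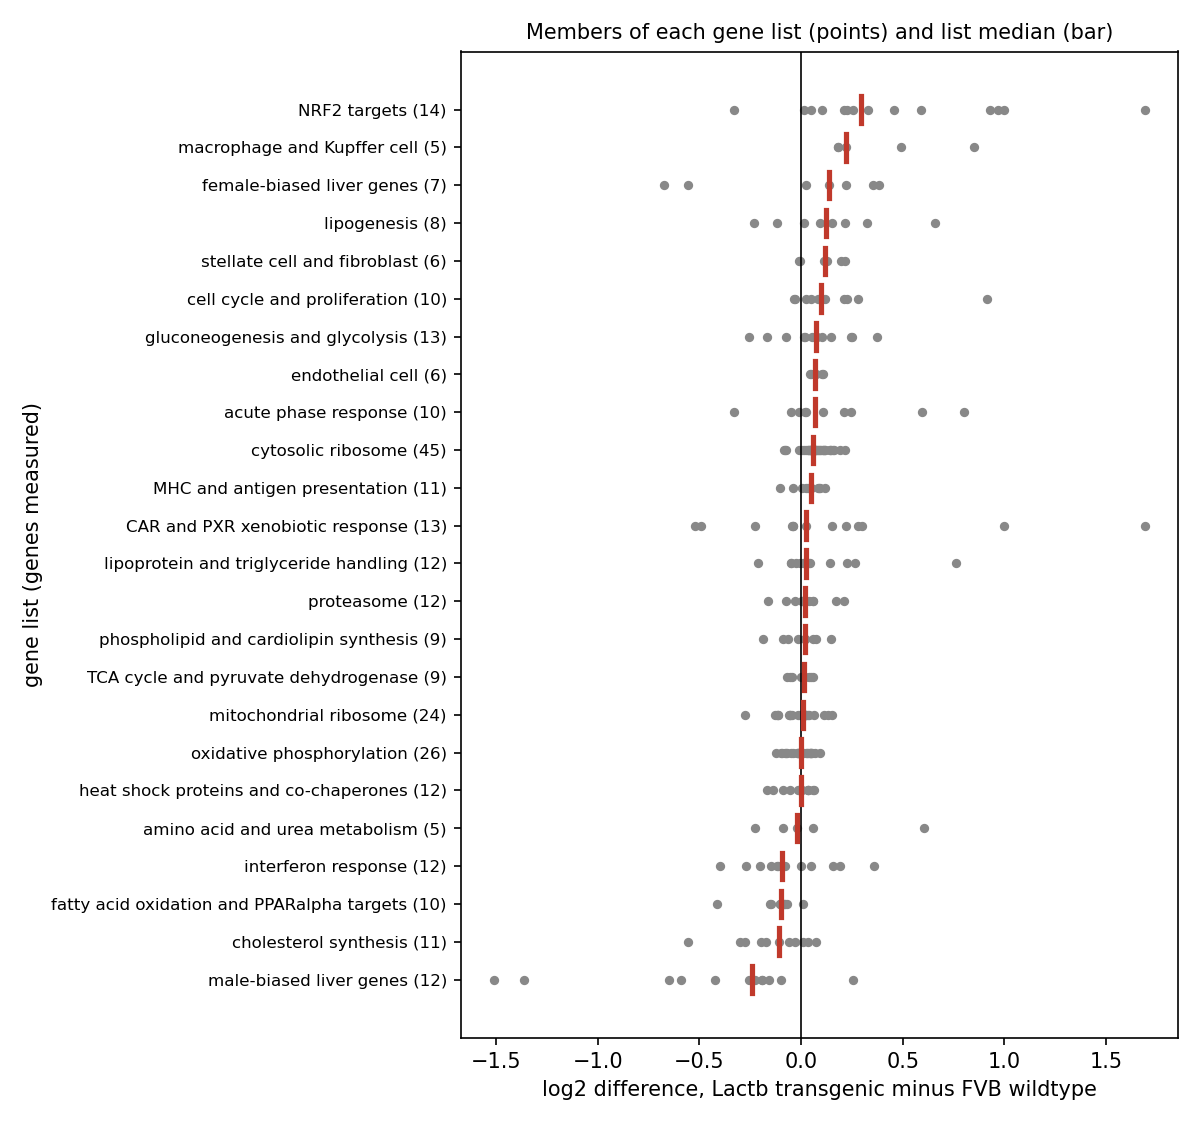
Log2 difference between transgenic and wildtype liver for every measured member (grey points) of the 24 tested gene lists, with the list median as a red bar and the number of measured genes in brackets. NRF2 targets have the highest median, 0.29, and male-biased liver genes the lowest, -0.24.

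The remaining metabolic lists were not called, and none of their members passed over all probes or adjusted over the list alone. Lipogenesis had 6 of 8 members higher, led by Acaca, the cytosolic acetyl-CoA carboxylase (0.33, SE 0.15), and Scd2 (0.66, SE 0.47). Cholesterol synthesis had 8 of 11 members lower, with Stard4 at -0.56 (SE 0.49) and Hmgcs1 at -0.17 (SE 0.20). Fatty acid oxidation and PPARalpha targets had 9 of 10 members lower (camera adjusted p = 0.0725), with the omega-hydroxylase Cyp4a10 at -0.42 (SE 0.18) and Acaa1b at -0.080. Gluconeogenesis and glycolysis had 10 of 13 members higher (camera adjusted p = 0.0725), with the glycolytic enzymes Eno1 at 0.25 (SE 0.089) and Gpi1 at 0.24 (SE 0.11). Lipoprotein and triglyceride handling had 7 of 12 members higher, with Mogat1 at 0.26 and Lrp1 at -0.21. Bile acid genes had 3 measured members, with Hsd3b7 at -0.17 and Slc10a1 at -0.44. Amino acid and urea metabolism had 2 of 5 members higher, with Ddc at 0.60 (SE 0.29) and Tdo2 at -0.23. The CAR and PXR response, genes induced by foreign compounds, had 7 of 13 members higher, with Gstm3 at 1.69 and Cyp2c37 at -0.49.

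Lists of the respiratory chain, the TCA cycle, the mitochondrial ribosome and phospholipids were not called. Oxidative phosphorylation had 13 of 26 members higher and a median of 0, with Ndufs4 at 0.091 and Ndufb8 at 0.069. The mitochondrial ribosome had 13 of 24 members higher, with Mrps12 at -0.27 (SE 0.15) and Mrpl23 at 0.13. The TCA cycle list had 6 of 9 members higher, with Dlst at -0.056 and Idh3b at 0.048. Phospholipid and cardiolipin synthesis had 5 of 9 members higher, with Pisd, the mitochondrial phosphatidylserine decarboxylase, at -0.19 (SE 0.092) and the cardiolipin synthase Crls1 at 0.15. The camera adjusted p of these 4 lists lay between 0.902 and 0.904.

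Stress, growth and regulatory lists were not called either, again with 0 members past the threshold over all probes or adjusted over the list alone. Female-biased liver genes had 5 of 7 members higher, with the prolactin receptor Prlr at -0.68 (SE 0.32) and Acot3 at -0.56. The interferon response had 7 of 12 members lower, with the antiviral Mx2 at -0.40 (SE 0.17). Cell cycle genes had 8 of 10 members higher (camera adjusted p = 0.0725), with Plk1 at 0.23 and Birc5 at 0.21. The acute phase list had 7 of 10 higher, with Orm1 at 0.21 and Saa1 at 0.80 (SE 0.53). MHC genes had 9 of 11 higher, with B2m at -0.10 and Psmb10 at 0.12. Heat shock genes had 6 of 12 higher, with Fkbp4 at -0.17 and Hsf1 at -0.055. Proteasome genes had 9 of 12 higher, with Psmd8 at 0.21 and Psmb5 at 0.17. Lists with fewer than 5 measured members were not tested. Their values were Rora at -0.095 and Nr1d2 at -0.13 for the circadian clock, Dnajb9 at -0.085 and Hspa5 at -0.11 for ER stress, and Klf2 at 0.16 and Sgk1 at 0.36 for immediate early genes. Candidate obesity genes gave Ppm1l at -0.17 and Gk at -0.12, and the neighbours of Lactb on its chromosome gave Rps27l at 0.16 (SE 0.11) and Rab8b at 0.19 (SE 0.16). For 6 lists the median, the mean or, where tested, the camera direction differed in sign: female-biased genes (median 0.14, mean -0.015, camera downward), candidate obesity genes (median -0.019, mean 0.14), amino acid metabolism, phospholipid synthesis, the mitochondrial ribosome and oxidative phosphorylation.

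Markers of other liver cells were not called as lists, and none of their members passed over all probes or adjusted over the list alone. All 5 measured macrophage markers had a higher mean in transgenic liver (camera adjusted p = 0.0725, and adjusted p = 0.79 with an estimated correlation), with Csf1r at 0.18 (SE 0.15) and lysozyme Lyz2 at 0.85 (SE 0.69; 0.023 to 1.99 under other settings). All 6 endothelial markers were higher, with Clec4g at 0.11 and Emcn at 0.10 (camera adjusted p = 0.198). Stellate cell and fibroblast markers had 4 of 6 higher, with Colec11 at 0.11 and Dcn at 0.12 (camera adjusted p = 0.408). The lists too small to test gave Cxcr2 at 0.15 and S100a9 at 0.48 for neutrophils, Spp1 at 0.62 and Cldn4 at -0.017 for cholangiocytes, and Cd3e at -0.025 for T cells. Ighm at -0.31 and Igkc at -0.028 stood for B cells, Hbb-b1 at -0.083 and Hbb-b2 at -0.18 for red cells, and Car3 at -0.20 and Fabp4 at 0.087 for adipocytes. Upk3b at 0.14 and Krt8 at 0.44 stood for mesothelium and gut, and Cel at -0.12 and Cela2a at -0.040 for pancreas. Serpina1a at -0.31 and Trf at 0.039 stood for hepatocytes. Of 8 muscle markers only 1 had a named probe, and it was not detected on enough arrays to be tested. Of the 5 genes of the male check 4 had a named probe, and only Kdm5d was detected on enough arrays, close to background (-0.037). The sex of the animals was therefore not checked on these data and rests on the submitters' description.

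The largest differences among these livers cut across the genotype labels. The first principal component of the 11317 tested probes held 57.2% of the variance, against 7.1% for the second. Transgenic replicates 1 and 2 and wildtype replicates 1, 2, 8 and 9 lay at its lower end, with coordinates from -31.1 to -25.9. Wildtype replicates 3 and 7 lay between, at -2.4 and 6.9, and the other 8 animals at 16.6 to 25.6. The mean coordinate was 7.5 ± 25.8 (SD, n = 7) in transgenic and -5.8 ± 22.8 (SD, n = 9) in wildtype animals, a difference that did not pass an exact permutation test (two-sided p = 0.281). In all, 7 animals had a coordinate below 0 (2 transgenic, 5 wildtype) and 9 had one above 0 (5 transgenic, 4 wildtype), numbers equal to the sizes of the labelled groups. Within a genotype, the 6 pairs of animals that share the number in their titles lay 4.5 apart on average, against 26.7 for all pairs of a genotype (permutation test within genotypes, chosen after seeing the data, one-sided p = 0.00667). The 5 pairs that share a number across genotypes lay 45.3 apart, and over all 11 pairs the distance was 23.0 against 27.1 for all pairs (permutation test, one-sided p = 0.224). The arrays with a coordinate below 0 detected 9907 to 10252 probes and those above 0 detected 10690 to 11564.

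The genes at the ends of this axis were chosen after their values were seen, as the 12 highest and the 12 lowest slopes per SD of the coordinate. The axis was computed from the same probes, so these slopes are a description and were not tested. High slopes belonged to Gpnmb, a lysosomal glycoprotein (2.74 log2 units per SD of the axis), Lpl, lipoprotein lipase (1.77), the macrophage elastase Mmp12 (1.62), the tetraspanin Cd63 (1.56) and Lyz2 (1.52). The deposited intensity of Mmp12 was between -11.3 and 9.5 in the 6 animals at the lower end, 129.0 and 155.9 in wildtype replicates 3 and 7, and 410.2 to 770.2 in the others. Others were those of the glutathione S-transferases Gstm3 (1.58) and Gsta2 (1.43), Prom1 (1.63), the female-biased cytochrome Cyp2b13 (with a slope between those of Lpl and Prom1), the annexin Anxa5 (1.46), the cell cycle inhibitor Cdkn1a (1.46) and Uap1l1 (1.45). Low slopes belonged to the male-biased Mup4 (-2.07), Mup2 (-2.05) and Susd4 (-1.99). Members of the cholesterol synthesis list with low slopes were Fdps (-1.06), Stard4 (-1.06), Nsdhl (-1.04) and Cyp51 (-1.02). The others were Hsd3b2 (-1.27), Lrtm1 (-1.11), Cyp2c50 (-1.05), Dct (-1.03) and Ttc39c (-0.95).

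The slopes of the fixed lists were not tested either. Over all tested probes 45.1% of the slopes were above 0, with a median of -0.015. All 11 measured members of the cholesterol synthesis list had a slope below 0 (median -0.71), as had 11 of 12 male-biased genes (median -0.51). Slopes were above 0 for all 5 macrophage markers (median 0.49), 13 of 14 NRF2 targets (median 0.37), 42 of 45 cytosolic ribosomal protein genes (median 0.11) and 5 of 7 female-biased genes (median 0.44). The medians of oxidative phosphorylation (-0.03) and the mitochondrial ribosome (-0.01) were close to 0. The 3 hepatocyte genes had slopes of -0.02 (Trf, transferrin), -0.09 (Apoa1, an apolipoprotein) and -0.61 (Serpina1a, a protease inhibitor). With the coordinate as a covariate, an alternative chosen after seeing the data, limma called 0 probes between the genotypes (384 at an unadjusted p under 0.05). The male-biased list then had a median difference of -0.056 (adjusted p = 0.633), the ribosomal list one of 0.016 (adjusted p = 0.351) and NRF2 targets one of 0.14 (adjusted p = 2.33e-04, and adjusted p = 0.14 with an estimated correlation).

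**Figure D3:**
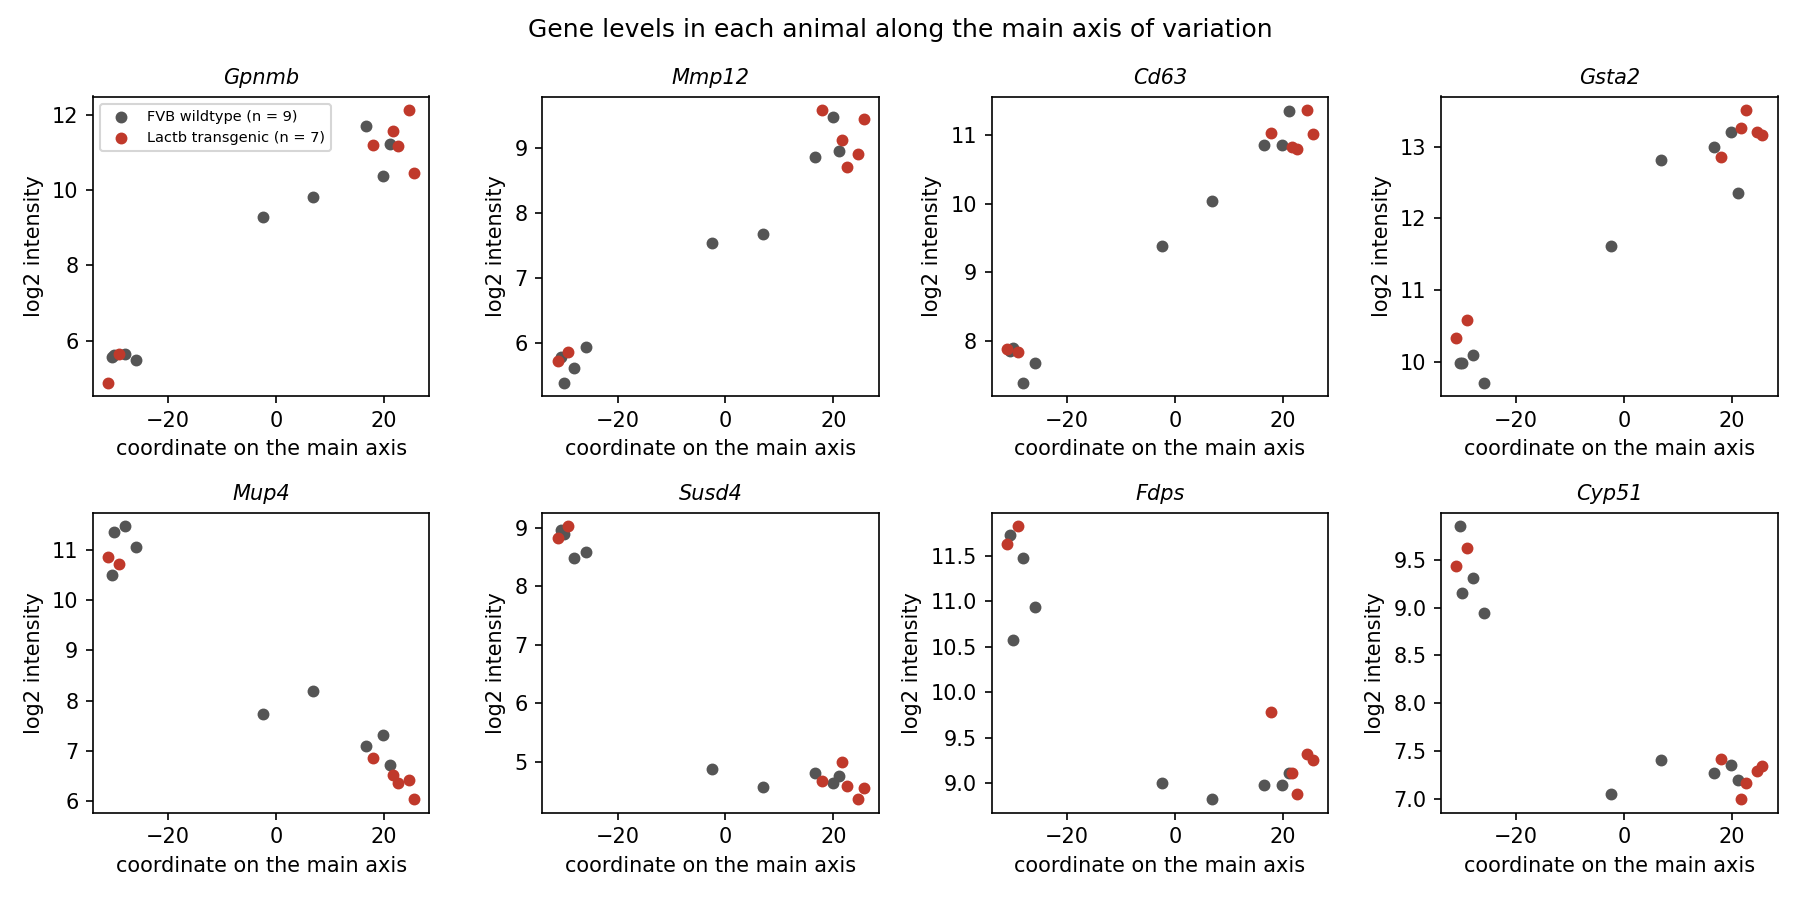
Log2 intensity of 8 genes in each animal against its coordinate on the first principal component, with wildtype in grey and transgenic in red; the coordinate has no unit. Gpnmb, Mmp12, Cd63 and Gsta2 have slopes of 1.43 to 2.74 log2 units per SD and Mup4, Susd4, Fdps and Cyp51 slopes of -2.07 to -1.02, and animals of both genotypes lie at each end.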

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

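Among the tests in this part, those of scaling, of labelled genotype, of an exchange of all labels, of title numbers within genotypes, of hepatocyte dilution and of the main axis as a source of list shifts were chosen after the results were seen.

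Within a genotype, 6 of 250 sets of values had an animal far from the others, where chance gives about 12.5. Ndufs4 was highest in wildtype replicate 4 (11.75, next 11.57), and Mup1 was lowest in wildtype replicate 5 (14.53, next 15.18). Csf1r was highest in wildtype replicate 5 (8.74, next 8.16), and Cxcr2 in wildtype replicate 1 (6.74, next 6.26). Saa1 was lowest in transgenic replicate 2 (9.56, next 11.39), and Clec4g was highest in transgenic replicate 6 (12.55, next 12.39).

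The axis that holds 57.2% of the variance joins the macrophage, sex-biased and cholesterol synthesis lists and separates animals within each genotype. Scaling of the arrays is argued against, since quantile normalization of the deposited values, with no background correction, left the share of variance on the axis at 0.97 times that before (47.7% against 49.3%). Weaker sensitivity of some arrays is argued against too, since over the 7787 probes detected on all arrays the share was 1.03 times that over all tested probes. The labelled genotype is not the cause of the axis as a whole, as 2 transgenic animals lie at its lower end and 4 wildtype animals above 0 (exact permutation test, two-sided p = 0.281). Dilution of hepatocyte RNA by other cells cannot be told apart from a change inside hepatocytes: the 6 genes of the hepatocyte and lipoprotein lists that other liver cells hardly make had a median slope of -0.12 per SD of the axis, against -0.51 for male-biased genes, but they ran from -0.61 (Serpina1a) to 0.04 (Apoa2), and those with flat slopes are among the brightest probes.

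Within a genotype, animals that share a title number lie close on the axis (4.5 apart against 26.7; permutation test within genotypes, one-sided p = 0.00667), so something shared by such animals, biological or technical, is a candidate for the source of the axis. They also follow each other in the order of the samples, so the number cannot be told apart from that order. What the number stands for is not given in the labels used here. The handling of the tissue stays open and was not tested. The sex of the animals was not tested as a source either, because the male check could not be read. Wrong genotype labels stay open too: the 7 animals below 0 and 9 above 0 have the sizes of the groups, yet 5 transgenic and 5 wildtype animals would need the other label for the sides to match them.

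The 3 lists called with the preset correlation run along that axis, on which transgenic animals lie higher by chance or otherwise. With the coordinate as a covariate the male-biased median went from -0.24 to -0.056 (adjusted p = 0.633) and the ribosomal median from 0.061 to 0.016 (adjusted p = 0.351), so for these lists the position of the animals on the axis is a candidate explanation. NRF2 targets went from 0.29 to 0.14 and were still called (adjusted p = 2.33e-04), but not with an estimated correlation (adjusted p = 0.14), which leaves the axis open as a part of their shift. Among 100 splits of the 16 arrays into 7 and 9, 64 gave as many called lists as the real 3, and the highest other split gave 9, so chance cannot be excluded.

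With 0 probes called by the real split, all 100 splits must call as many (highest other 1), so this count decides nothing. The 332 probes at an unadjusted p under 0.05 were matched by 57 of the 100 splits, with 3047 in the highest other split, so chance cannot be excluded for them. A split with several times the real count points to a structure of the samples.

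No probe looked like a strongly expressed transgene. The filter on dim probes is argued against as the reason, since 0 of the 24048 probes were both over 1 log2 unit higher and higher in every transgenic than in every wildtype array. For an exchange of all labels, 0 probes were both over 1 log2 unit lower and lower in every transgenic than in every wildtype array. Only 2 probes were lower in all, by at most 0.43. The labelled direction gave 0 such probes as well, so these counts cannot decide for or against an exchange. An exchange of single labels cannot be told apart here from a transgene whose RNA no probe reads, because 0 probes can be named Lactb. The direction of each difference therefore rests on the labels.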

How the results depend on the processing

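The fits with the main axis or residual components as covariates, with the title number within a genotype as a random block, and the fit without 2 wildtype arrays were chosen after the results were seen. limma called 0 probes without any single animal and under every setting except residual components: 231 calls with the first and 317 with the first 2 as covariates. These components are by construction uncorrelated with genotype, so they shrink the error and leave the group's part of the axis in place, and all 231 and all 317 calls follow the sign of the axis. The 332 of 11317 probes at an unadjusted p under 0.05 (127 higher, 205 lower) became 153 with median centring and 1197 with array weights. With no filter they were 875, but of 24048 probes. The title number gave 1509 as a fixed block (848 higher, 661 lower) and 193 as a random block within a genotype. In the fixed block, numbers 12 and 13 set transgenic replicates 3 to 6 (17.9 to 25.6 on the axis) against wildtype replicates 8 and 9 (-28.1 and -25.9). Number 9 set transgenic replicate 2 (-31.1) against wildtype replicate 3 (-2.4). The authors' values gave 142 higher and 136 lower. Without single animals that count ran from 219 to 797: 797 and 795 without transgenic replicates 1 and 2, 590, 583 and 219 without wildtype replicates 4, 5 and 9.

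The 3 called lists became 5 with median centring, 7 with the title number as a fixed block, 5 with array weights, 6 with the main axis as a covariate (of the 3, only NRF2 targets among them), and 0 with an estimated correlation, with fry, or with the main axis and an estimated correlation. Without single animals 2 to 6 lists were called: 5 without transgenic replicate 1, 2 or 3 or wildtype replicate 1, and 6 without wildtype replicate 5. NRF2 targets and the ribosome kept their call without any single animal (adjusted p up to 8.81e-04 and 0.00372). With the main axis as a covariate the ribosome (0.351) and male-biased genes (0.633) lost it. Male-biased genes also lost it on probes detected on all arrays (0.0515), with the title number within a genotype as a random block (0.0511), without transgenic replicates 3, 5 and 6 (0.0704, 0.0936, 0.0519) and without wildtype replicates 2 and 8 (0.0924, 0.0586), in a range of 4.20e-04 to 0.913 over the other settings. The cause was not tested.

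Of 103 named genes and probes 91 kept their direction under every alternative, and none passed the threshold (lowest adjusted p 0.252) except with residual components, where 10 passed with the first and 16 with the first 2, all 103 with the direction kept by construction. Size was less stable than direction: 90 of the 103, and 13 of the 24 genes of smallest p, moved over 1.5 times under some setting. Lrrc24 ran from 0.531 to 1.41, Rnd2 from 0.249 to 0.789, Rpap3 from 0.213 to 0.823, Gstm3 from 0.902 to 2.83, Lyz2 from 0.023 to 1.99 and S100a9 from 0.003 to 1.06, while Gstm2 stayed within 0.759 to 1.16. Reversed values were near 0 and their cause was not tested: with median centring Trf -0.001 and Cldn4 0.026; with the authors' values Cldn4 0.078; with the title number as a fixed block Cldn4 0.084 and Fabp4 -0.001; as a random block Igkc 0.015, and within a genotype as a random block Igkc 0.099; with array weights Cldn4 0.007. With the main axis as a covariate Stard4 was 0.027, Hmgcs1 0.007, Dlst 0.001, Nr1d2 0.036, Serpina1a 0.028, Igkc 0.004 and Cela2a 0.036. Leaving out single animals gave Cldn4 -0.058 to 0.062, Cd3e -0.096 to 0.043, Kdm5d -0.108 to 0.066, Igkc -0.201 to 0.129 and Cela2a -0.142 to 0.029. The axis held 33.7% (no filter) to 59.6% (offset of 50) of the variance, and its 24 named genes kept the sign of their slope. Slopes of genes near background at an end depend on the offset and background correction: Gpnmb reached 3.44, Prom1 2.42, Uap1l1 2.12, Dct -1.74 and Lrtm1 -1.71, Mmp12 ran from 1.32 to 2.41, and Susd4 was -1.45 with the offset of 50. The slide block and the Lactb level were not run.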

Other observations

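The test of the axis on lists in this part was chosen after the results were seen. With the coordinate on the main axis as a covariate, camera with its preset correlation called 6 lists between the genotypes, and 0 with an estimated correlation (lowest adjusted p = 0.14). Besides NRF2 targets these were cholesterol synthesis (median 0.19 higher in transgenic liver, adjusted p = 1.88e-05, and adjusted p = 0.261 with an estimated correlation) and lipogenesis (median 0.20, adjusted p = 0.00154, and adjusted p = 0.261 with an estimated correlation). Gluconeogenesis and glycolysis had a median of 0.097 (adjusted p = 0.0183, and adjusted p = 0.261 with an estimated correlation), and the interferon response one of -0.14 (adjusted p = 0.00668, and adjusted p = 0.509 with an estimated correlation). Female-biased genes had a median of -0.37 (adjusted p = 0.05, and adjusted p = 0.52 with an estimated correlation). Without the covariate the medians were -0.11 for cholesterol synthesis and 0.14 for female-biased genes, so the sign of both medians depends on it. The covariate assumes a straight line along the axis, which some genes did not follow. Wildtype replicates 3 and 7, between the ends, had Fdps at 9.01 and 8.83, against 10.57 to 11.82 at the lower end and 8.88 to 9.78 at the upper end. Nsdhl and Cyp51 behaved alike. The shift of cholesterol synthesis under the covariate may therefore come from this misfit, which was not tested.

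A pair of animals did not sit at either end of the axis. Wildtype replicate 3 had a Gpnmb intensity of 567.6 and a Mup2 intensity of 423.3, and wildtype replicate 7 had 868.5 and 872.8. In the 6 animals at the lower end Gpnmb lay between -24.6 and -0.9 and Mup2 between 3790.3 and 5583.3. In the other 8 Gpnmb lay between 1348.5 and 4441.3 and Mup2 between 84.2 and 445.2, a range that holds the Mup2 value of wildtype replicate 3. The pair was not intermediate for every gene. Susd4 was -28.2 and -21.6 in wildtype replicates 3 and 7, within the range of the other 8 (-31.2 to -14.8). Fdps was 456.2 and 417.8, below their range of 461.1 to 884.5 and far from the lower end (1403.1 to 3614.9).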
